A study of Pimephales promelas with 580 samples.

How the data were processed

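RNA from fathead minnow (Pimephales promelas), a small freshwater fish used in toxicity testing, was hybridised in a single colour (Cy3) to Agilent arrays in 580 samples. The labels put the arrays into 51 groups by chemical, dose, tissue and exposure time. They fall into 8 experiments that were analysed separately. Livers and male brains were exposed to 17α-ethynylestradiol (EE2), a synthetic estrogen. Male brains were exposed to the pyrethroid insecticide permethrin, the organophosphate insecticide terbufos or both. Brains and larvae were exposed to pyrethroids in the other experiments. Larvae exposed to bifenthrin, cypermethrin, esfenvalerate and permethrin at 2 doses each are called the 2-dose larval experiment, and those exposed to 1 dose of each chemical in 3 separately labelled runs are called the 3-run larval experiment. The design text and extraction protocol speak of ovary, whereas the sample labels say liver, brain or larvae. The sample labels were followed.

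Each array has its own scanner output with intensity values as deposited. Per the file headers, spot intensity was extracted with Agilent Feature Extraction, version 11.0.1.1 for 532 arrays and 9.5.1.1 for 48 arrays. The processed intensity is the background-corrected signal that this software writes, per the file headers. The authors also deposited 36 tables, each holding 1 treated group and its controls, with values on a log2 scale. The submitters' processing notes name Agilent Feature Extraction and limma without saying which step used which. Column medians of these deposited log2 tables lay between 7.21 and 8.19. Within a table the columns had nearly equal distributions, with quantiles that differed by at most 0.094, and each column correlated with its array's own log2 signal at r of at least 0.899 across probes. The slope against that signal ran from 0.41 to 1.29. The log2 scale, with no centring of probes, is therefore borne out by the scanner values. The background correction behind the tables stays unknown, and levels were not compared across tables because each was normalized separately.

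The smaller array design holds 15208 probes and the larger one 49849 probes. Neither the files nor the reference table used here pair these probes with gene names. Probes are therefore given by their identifier, with the probe sequence where a file lists one. The 33 gene lists that had been fixed beforehand, and the tests on them, were not run for that reason. It is also unknown which probes measure the same transcript, so that counts of probes are not counts of genes.

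The processed intensity was taken as log2, and each array's 75th percentile was subtracted. Control spots were left out, spots marked as outliers were set to missing, and repeated spots of a probe were averaged. A probe was kept when at least 50% of the arrays of at least 1 group were well above background. This left between 14063 and 14522 probes on the smaller design and between 30656 and 46017 on the larger one. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend in the variance), with all groups of an experiment sharing 1 estimate of the spread. In the 3-run larval experiment the run was a term of the fit. A probe was called at a Benjamini-Hochberg adjusted p under 0.05. In the 2-dose larval experiment every chemical was compared with the solvent controls that carry the same number in their titles. Unadjusted counts refer to p under 0.05.

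Probes were named by a rule fixed before the data were examined: the largest changes among called probes for which at least 75% of the treated arrays lay beyond the control median, with at most 2 risers and 2 fallers per comparison because no gene names were at hand. Where fewer than 5 probes were called, the probes with the smallest p were considered too. Fold changes of probes that were not well above background on some arrays depend on signal close to background.

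Likeness of profiles is the Spearman correlation of log2 fold changes across probes, which are not independent replicates. It was compared with values from random splits of control arrays of the same experiments. For likeness between runs, the chemical labels were permuted within runs (one-sided exact test, 576 permutations). Signature scores were chosen after the data had been seen: a score is the mean of the 100 most raised probes of 1 comparison minus the mean of its 100 most lowered probes, computed on each array of another experiment. The bifenthrin signature was chosen after a preliminary look at its scores. Permutation tests, all two-sided, compared scores between groups. They were exact where the regroupings were few enough to enumerate, and otherwise drew 100000 permutations, within runs for the 3-run experiment. The p-values were adjusted within each setting, over 115 tests in the main one. Tests against all 34 controls were adjusted separately.

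The limma steps were tested on simulated data with 200 changed probes per comparison. For the EE2 liver design, with 30656 probes, 64.0% of probes changed by 1 on the log2 scale and 86.0% of those changed by 2 were recovered. For the comparison of 3 esfenvalerate arrays with 9 controls, over 43679 probes, the shares were 45.0% and 82.0%. For cypermethrin at 1 µg/L in larvae on the smaller design, over 14464 probes, they were 68.0% and 92.0%. For bifenthrin at 0.593 µg/L in brain, over 14522 probes, they were 64.0% and 86.0%. For permethrin in the 3-run experiment, over 46017 probes, they were 96.0% and 99.0%. Calls on unchanged probes, nominally 5%, made up 9.6% of calls for EE2 liver, 7.3% for esfenvalerate, 6.4% for cypermethrin in larvae on the smaller design, 5.1% for bifenthrin in brain and 5.3% for permethrin in the 3 runs, each in 1 simulation. The simulated noise was independent between arrays and between probes. Random regroupings of the real arrays in the esfenvalerate comparison called up to 2343 probes, so the simulated shares cannot be carried over to the real arrays.

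Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, no filter on dim probes, the slide as a block, the authors' deposited log2 values, all 34 solvent controls, single runs, single slides, the scan day with the most arrays, and leaving out each of 3 esfenvalerate arrays. Normexp used the median signals, since the files of 532 arrays hold no mean signal. An alternative chosen after seeing the data left out arrays whose median correlation with the other arrays of their experiment fell more than 3 interquartile ranges below the lower quartile. In the 1.6 µg/L experiment the titles of treated and control arrays end in the same numbers 1 to 3, each on several arrays. Treated and control arrays of a number deviated together, with correlations across probes of 0.44, 0.69 and 0.59, and 54 of 62 arrays correlated best with their own number in the other group. This check was made after the count with the number as a block had been seen. In the other experiments the labels give no number that pairs single arrays. They do not say whether arrays come from separate fish or tanks, so p-values measure only the spread between these samples. The number of arrays limits the precision.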

Results

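The series profiled liver, brain and whole larvae of fathead minnow after exposure to an estrogen or to insecticides. Its title names connectivity mapping, in which chemicals are linked by the likeness of their expression profiles. The EE2 experiments held 16 liver arrays and 48 male brain arrays. Another 48 male brain arrays covered permethrin, terbufos and their mixture. Bifenthrin and cypermethrin were tested on 57 brain arrays and 55 larval arrays of the smaller design. On the larger design, the 2-dose larval experiment held 108 arrays, the 3-run larval experiment 183 arrays, and an experiment with bifenthrin at 1.6 µg/L 65 arrays. The median share of probes well above background was 54.9% in liver and between 80.6% and 89.9% in the other experiments.

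The liver comparison asked how EE2 at 25 ng/L changed expression within 72 h. Probe SINGLET_30631 stood at 10.02 ± 0.29 (SD, n = 8) in EE2 livers and at -2.87 ± 1.96 (n = 8) in control livers, on the log2 scale relative to the 75th percentile. This is a rise of 12.89 (limma adjusted p = 1.5e-10), seen in 8 of 8 EE2 arrays. SINGLET_903 rose by 12.51 with an SE of 0.43 (adjusted p = 7.3e-13), again in 8 of 8 arrays. Both probes were well above background on 8 EE2 arrays, and on 5 and 4 control arrays respectively. SINGLET_6261 fell by 5.94 with an SE of 1.01 (adjusted p = 3e-04) and SINGLET_46373 fell by 5.84 with an SE of 0.99 (adjusted p = 0.00028). Each lay below the control median on 8 of 8 EE2 arrays. In all, 4941 probes rose and 4878 fell among 30656, and 3973 of these 9819 changed at least 2-fold. EE2 arrays were dimmer, with a 75th percentile of 8.70 ± 0.12 (SD, n = 8) against 9.28 ± 0.18 (n = 8) in controls (exact permutation p = 0.00016). With the slide as a block 3706 probes rose and 3499 fell, and without the filter on dim probes 15788 were called in all. Most control arrays lay on slide 1 and most EE2 arrays on slide 2, so that slide and treatment overlap in the main count. On slide 1 alone 751 rose and 339 fell, and on slide 2 alone 2150 rose and 1832 fell, each with few arrays of 1 group. Normexp background correction gave 7995 risers and 4352 fallers, which is 64.8% risers in place of 50.3%.

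In male brain after 96 h of EE2, a small set of probes rose with the dose. UF_Ppr_AF_106707, with the probe sequence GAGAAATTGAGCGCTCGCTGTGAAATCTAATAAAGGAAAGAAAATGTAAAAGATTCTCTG, stood at -4.59 ± 0.71 in controls, -4.36 ± 1.27 at 0.1 ng/L, -2.38 ± 0.96 at 1 ng/L and 1.42 ± 0.80 at 10 ng/L (log2, SD, n = 12 each). It rose by 2.21 at 1 ng/L (limma adjusted p = 0.02) and by 6.01 at 10 ng/L (adjusted p = 5.7e-16), on 12 of 12 arrays at either dose. SINGLET_4251 rose by 4.18 at 10 ng/L with an SE of 0.40 (adjusted p = 7.3e-10), on 12 of 12 arrays. It was well above background on 1 of 12 control arrays, so that the size of this rise depends on signal near background. Its differences at 0.1 and 1 ng/L were 0.26 and 1.35, neither of which passed the test (adjusted p = 0.99 for both). In EE2 livers the same probes rose by 3.95 (UF_Ppr_AF_106707, adjusted p = 0.0075) and by 3.10 (SINGLET_4251, adjusted p = 3e-05). At 10 ng/L 5 probes rose and none of 43115 fell, with 1214 probes at an unadjusted p under 0.05. Of these 5 risers, 4 had also risen in liver, where independent lists would share 0.8. These 4 need not be separate transcripts: UF_Ppr_AF_103929 and SINGLET_30293 rose by 0.74 and 0.68 in brain and by 1.57 and 1.59 in liver. At 1 ng/L 1 probe rose, and this call was lost with the slide as a block, with normexp and on 1 scan day alone. At 0.1 ng/L limma called 0 probes, with 1892 at an unadjusted p under 0.05, and the slide block gave 2. The linear trend over doses called 5 probes, all rising, and 8 with normexp.

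**Figure D1:**
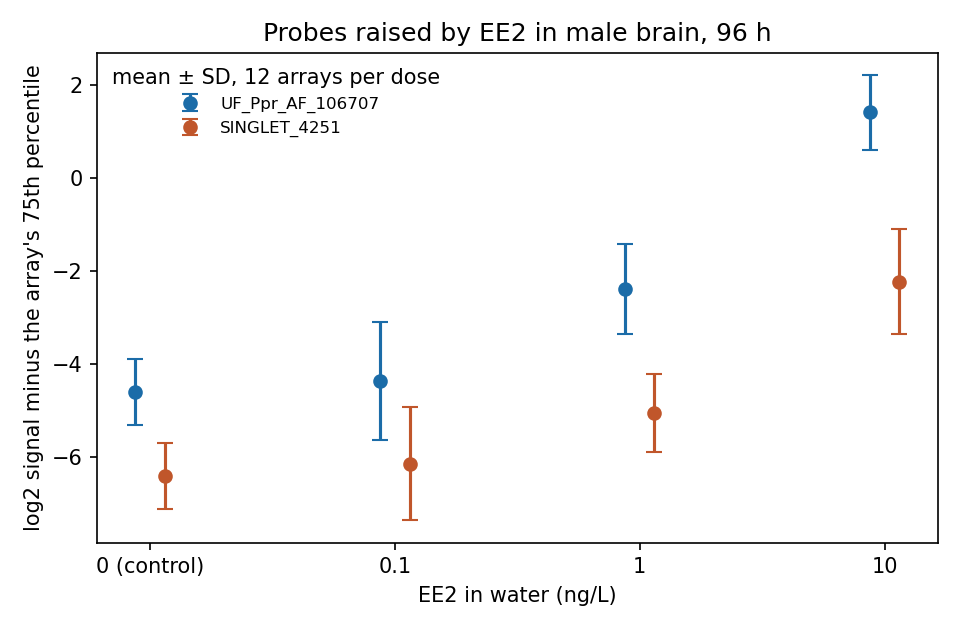
Signal of probes UF_Ppr_AF_106707 and SINGLET_4251 (vertical axis, log2 signal minus the array's 75th percentile) in male brain at each EE2 dose (horizontal axis, ng/L, equally spaced). Points are means and bars SD over 12 arrays; UF_Ppr_AF_106707 goes from -4.59 in controls to 1.42 at 10 ng/L.

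Permethrin at 7.5 µg/L, terbufos at 57.5 µg/L and their mixture were compared with the same 13 control brains after 72 h. Terbufos, an inhibitor of acetylcholinesterase, raised 22 probes and lowered 23 of 14063. UF_Ppr_AF_114628 (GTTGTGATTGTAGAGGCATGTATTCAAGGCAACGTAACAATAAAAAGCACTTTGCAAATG) rose by 3.97 with an SE of 0.78 (limma adjusted p = 0.0043), above the control median on 11 of 13 arrays. UF_Ppr_AF_103842 (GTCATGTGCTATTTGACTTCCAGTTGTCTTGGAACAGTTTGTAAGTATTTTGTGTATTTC) fell by 1.17 with terbufos (adjusted p = 1e-06, 13 of 13 arrays) and by 0.84 with permethrin (adjusted p = 0.0014, 16 of 16 arrays). Its difference with the mixture was -0.26 with an SE of 0.18 (adjusted p = 0.98). These comparisons share their controls, so that chance deviations of the controls enter each of them. Permethrin raised 1 probe and lowered 2, with 3128 probes at an unadjusted p under 0.05 and a median difference over all probes of 0.14 on the log2 scale. Its 3 calls became 0 with normexp, 1 with the slide as a block and 8 with the authors' deposited values. For the mixture, on 6 arrays, limma called 0 probes, with 929 at an unadjusted p under 0.05. The mixture departed from the sum of both single effects for 8 probes, of which 5 were higher and 3 lower than the sum, and for 3 probes with normexp. The terbufos count of 45 was 25 on the scan day with the most arrays, 68 with normexp and 192 with the authors' deposited values. It was 97 without 2 low-correlation arrays, an alternative chosen after seeing the data. Terbufos arrays were scanned on 1 day and the controls on 2.

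Bifenthrin at 0.148 and 0.593 µg/L and cypermethrin at 0.25 and 1 µg/L were tested in brain after 72 h and in larvae after 48 h on the smaller design, with 8 to 10 arrays per group. Limma called 0 probes in each of these comparisons. In brain, 472 and 368 probes had an unadjusted p under 0.05 for the lower and the higher bifenthrin dose, and 717 and 855 for the cypermethrin doses. In larvae the counts were 363 and 157 for bifenthrin and 335 and 645 for cypermethrin. Other settings gave at most 2 calls in any of them. The lowest adjusted p in larvae was 0.059, for UF_Ppr_AF_115747 at the higher cypermethrin dose, with a difference of -2.42 (SE 0.47). For 67.8% to 77.6% of the probes, the 95% interval of the difference lay within a 2-fold change either way.

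Bifenthrin at 1.6 µg/L raised 13142 probes and lowered 9051 of 41135 in larvae after 48 h. UF_Ppr_AF_109937 (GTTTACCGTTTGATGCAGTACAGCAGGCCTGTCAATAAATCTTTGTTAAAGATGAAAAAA) stood at 5.45 ± 0.18 (SD, n = 32) against -0.37 ± 1.41 (n = 33) in controls. It rose by 5.83 (limma adjusted p = 3.3e-32) on 32 of 32 arrays, and CONTIG5672 rose by the same amount. Whether both probes measure the same transcript is not known. Arrays of this experiment deviated together by the number in their titles. The p-values count every array as a replicate, and the labels do not say whether the arrays are independent. UF_Ppr_AF_114880 (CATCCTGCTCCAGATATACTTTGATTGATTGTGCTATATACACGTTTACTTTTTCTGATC) fell by 4.27 with an SE of 0.22 (adjusted p = 2.4e-27) and SINGLET_2650 fell 18.4-fold with an SE of 0.25 on the log2 scale (adjusted p = 4.7e-24), both on 32 of 32 arrays. Most calls were modest in size: 2619 of the 22193 reached 2-fold, and the median absolute change of called probes was 0.46. The balance of risers and fallers depended on the scaling. Risers made up 59.2% of calls here, 45.1% after quantile normalization and 46.7% with the authors' deposited values.

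The 3-run experiment exposed larvae to 4 pyrethroids for 48 h: bifenthrin at 0.15, cypermethrin at 0.2, esfenvalerate at 0.15 and permethrin at 0.4 µg/L, against 58 solvent controls. Bifenthrin raised 7440 probes and lowered 7596 of 46017. UF_Ppr_AF_109937 rose by 4.33 (limma adjusted p = 3.9e-23), from 0.34 ± 1.79 (SD, n = 58) to 4.69 ± 0.76 (n = 32), on 32 of 32 arrays. Its means in bifenthrin larvae were 5.12, 4.79 and 4.16 in runs 1, 2 and 3, against 1.61, 0.05 and -0.59 in the controls of those runs. UF_Ppr_AF_119067 (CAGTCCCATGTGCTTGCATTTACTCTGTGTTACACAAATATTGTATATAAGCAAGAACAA) fell by 1.98 with an SE of 0.15 (adjusted p = 1e-25) on 31 of 32 arrays, and fell by 3.37 at 1.6 µg/L. SINGLET_32225 fell by 2.43 with an SE of 0.22 (adjusted p = 2e-20) on 32 of 32 arrays, whereas its difference at 1.6 µg/L was -0.22 with an SE of 0.38 (adjusted p = 0.64). Run 1 alone gave 9286 calls for bifenthrin, run 2 gave 7392 and run 3 gave 4595. For cypermethrin, esfenvalerate and permethrin limma called 0 probes each, with 1193, 1081 and 1636 at an unadjusted p under 0.05. Single runs gave at most 9 calls for these chemicals. For at least 99.5% of the probes the 95% interval of their difference from controls lay within a 2-fold change. The effect of a chemical depended on the run for 74 probes of 44784, for 128 with the slide as a block and for 44 with normexp.

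Profiles of the same chemical in different runs correlated at a mean Spearman rho of 0.065 across probes, against -0.008 for different chemicals (excess 0.073, exact permutation p = 0.064). Bifenthrin profiles correlated at 0.56, 0.59 and 0.37 between pairs of runs. The mean was -0.05 for cypermethrin, -0.09 for esfenvalerate and -0.11 for permethrin.

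**Figure D2:**
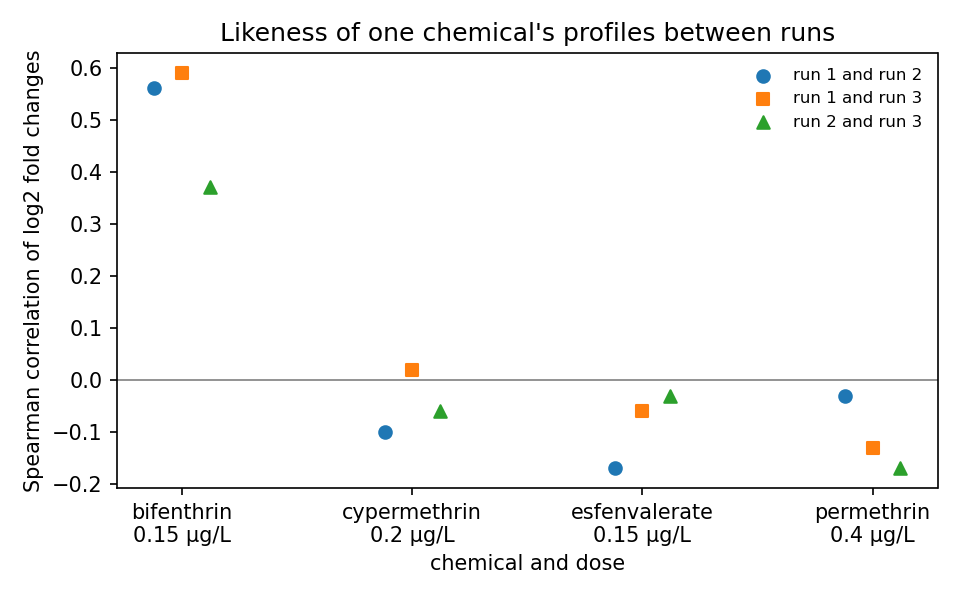
Spearman correlation of log2 fold changes across probes (vertical axis) between pairs of runs, for each of the 4 chemicals (horizontal axis); every point is 1 pair of runs. The bifenthrin points lie at 0.37 to 0.59, and the others between -0.17 and 0.02.

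The pyrethroids differ in structure: cypermethrin and esfenvalerate carry a cyano group on the alcohol part, and bifenthrin and permethrin do not. At the matched dose of 0.15 µg/L, bifenthrin was higher than esfenvalerate for 5334 probes and lower for 5201. SINGLET_45700 was higher by 3.69 (limma adjusted p = 3.2e-15) and UF_Ppr_AF_119067 lower, with a difference of -1.85 (adjusted p = 6e-18). Bifenthrin arrays lay beyond the esfenvalerate median on 32 of 32 and 31 of 32 arrays. Single runs gave 4546, 5255 and 1794 such probes. Against solvent controls bifenthrin had 15036 calls and esfenvalerate 0, but permethrin, which also lacks the cyano group, had 0 too. This contrast therefore cannot be read as a difference between the structural classes. Both cyano pyrethroids were compared at matched doses in the 2-dose experiment, each relative to its own solvent controls. At 0.5 µg/L 167 probes had a higher and 420 a lower response to cypermethrin than to esfenvalerate. At 1 µg/L the responses differed for 8 probes, with 4453 at an unadjusted p under 0.05. The 95% interval at that dose excluded a 2-fold difference for 48.4% of the probes only. Leaving out single esfenvalerate arrays moved this count between 0 and 27. With all 34 solvent controls pooled, the controls cancel out, and the treated arrays of both chemicals are set directly against each other. The counts were then 0 at 0.5 µg/L and 845 at 1 µg/L. These arrays carry different title numbers, whose solvent controls differed for 4356 probes, so that difference enters both counts. Which dose shows the larger difference thus depends on whether each chemical's own controls are subtracted.

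In the 2-dose experiment bifenthrin at 0.3 µg/L raised 4124 probes and lowered 8126 of 43679. SINGLET_45567 rose by 3.56 with an SE of 0.54 (limma adjusted p = 2.6e-07) on 10 of 10 arrays, but was well above background on 1 of 8 control arrays, so that the size depends on signal near background. UF_Ppr_AF_109616 (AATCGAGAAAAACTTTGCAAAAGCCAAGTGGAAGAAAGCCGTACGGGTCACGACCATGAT) fell by 2.35 with an SE of 0.32 (adjusted p = 1.4e-08) on 10 of 10 arrays. The count of 12250 was 7259 with normexp and 2507 with all 34 solvent controls. The median difference over all probes was -0.13, which was not subtracted from these changes. At 0.15 µg/L limma called 4 probes for bifenthrin, with 5184 at an unadjusted p under 0.05. This count depended on the controls and settings: it was 6256 with all 34 solvent controls, 24 after quantile normalization and 0 with normexp. UF_Ppr_AF_109937 differed from controls by 0.30 (SE 0.58) at 0.15 µg/L and by 0.92 (SE 0.59) at 0.3 µg/L, neither passing the test (adjusted p = 0.85 and 0.25). Cypermethrin at 0.5 µg/L raised 494 probes and lowered 763. UF_Ppr_AF_100015 (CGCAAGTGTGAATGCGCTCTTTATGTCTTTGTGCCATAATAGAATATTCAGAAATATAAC) rose by 2.73 with an SE of 0.36 (adjusted p = 2.5e-08) and SINGLET_624 fell by 2.04 with an SE of 0.24 (adjusted p = 1.2e-09), both on 10 of 10 arrays. The count of 1257 fell to 152 on the scan day with the most arrays and to 56 with all 34 solvent controls. At 1 µg/L limma called 3 probes for cypermethrin, a count that 8 of 100 random regroupings also reached. It was 0 with the slide as a block and with the authors' deposited values, and 392 with all 34 solvent controls. Normexp gave 18.6% risers in place of 39.3% for cypermethrin at 0.5 µg/L.

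Permethrin at 3.13 µg/L raised 1276 probes and lowered 590. SINGLET_29876 fell by 2.67 with an SE of 0.55 (limma adjusted p = 0.017) on 11 of 11 arrays. This count depended on the arrays and settings used: 182 probes were called with the slide as a block, 14 without low-correlation arrays, and 0 both on the scan day with the most arrays and with all 34 solvent controls. Normexp called more, 5666 higher and 646 lower, and quantile normalization called more too. Risers were 68.4% of the calls at 3.13 µg/L and 89.8% with normexp. With the authors' deposited values they were 4.5%, but of few calls, 1 higher and 21 lower. At 1.56 µg/L limma called 0 probes, with 3792 at an unadjusted p under 0.05, and 10 probes with normexp. Esfenvalerate gave 0 calls at 0.5 µg/L (limma), with 3525 at an unadjusted p under 0.05, and 19 calls on the scan day with the most arrays. At 1 µg/L, on 3 arrays, esfenvalerate raised 2 probes and lowered 6. UF_Ppr_AF_107164 (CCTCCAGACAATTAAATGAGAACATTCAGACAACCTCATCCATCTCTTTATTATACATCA) rose by 1.12 with an SE of 0.22 (adjusted p = 0.021) on 3 of 3 arrays. Without esfenvalerate replicate 2 no probe was called, and the other arrays left out in turn gave up to 17. The authors' deposited values gave 46, and 45 of 100 random regroupings reached the 8 calls.

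Profiles were also compared between experiments, and between groups of the 2-dose experiment, that share no controls. Many pairs were compared, with no adjustment for their number. EE2 in liver correlated with EE2 at 10 ng/L in male brain at -0.08, inside the range of control splits. Bifenthrin at 1.6 µg/L and bifenthrin in the 3-run experiment correlated at rho = 0.58 across 41036 probes. Random splits of the control arrays gave -0.36 to 0.35. Of the probes called higher in both, 5724 were shared where independent lists would share 2347.3, and 4717 were shared among those lower in both, against 1535.8. Opposite calls numbered 211 and 181. The bifenthrin profile of the 2-dose experiment at 0.3 µg/L correlated with these at -0.05 and -0.06, inside the range of control splits, and at 0.15 µg/L the 2-dose profile correlated with the 3 runs at 0.00. With larvae of the smaller design it correlated at 0.31 for 0.593 µg/L and 0.20 for 0.148 µg/L, where control splits reached 0.29 and 0.19. Bifenthrin at 0.15 µg/L correlated with 0.148 µg/L there at 0.29 (splits up to 0.19) and with 0.593 µg/L at 0.28 (5 of 100 splits as high). For cypermethrin, 1 µg/L in both experiments correlated at 0.37 (splits up to 0.21), whereas 0.5 µg/L correlated with 1 µg/L of the smaller design at 0.04. Cypermethrin at 0.25 µg/L of the smaller design correlated with 1 µg/L of the 2-dose experiment at 0.33 and with 0.5 µg/L at 0.21 (splits up to 0.2 for both). Likeness was not limited to the same chemical: in the 2-dose experiment bifenthrin at 0.3 µg/L and cypermethrin at 0.5 µg/L, with different solvent controls, correlated at 0.54 (splits up to 0.27). They shared 254 probes called higher and 686 called lower, where independent lists would share 46.6 and 141.9, and 0 opposite calls. For pairs within this experiment the splits divided only the solvent controls of 1 chemical. Such splits cannot tell likeness of chemicals from technical effects that both profiles share. Other pairs in that experiment went apart or showed no likeness: bifenthrin at 0.15 and cypermethrin at 1 µg/L correlated with permethrin at 3.13 µg/L at -0.49 and -0.35 (splits down to -0.30 and -0.34), and bifenthrin at 0.3 with cypermethrin at 1 µg/L at 0.04. The esfenvalerate profile at 1 µg/L in the 2-dose experiment correlated with bifenthrin in the 3-run experiment at 0.51, where control splits reached 0.23, and that at 0.5 µg/L at 0.33. With bifenthrin at 1.6 µg/L the values were 0.39 for the higher dose (splits up to 0.32) and 0.19 for the lower, where 30 of 100 splits were as high. In every pair of a 2-dose profile with another experiment, the splits divided only the solvent controls of that profile's own title number. They cannot show an offset between control sets, which could also give such likeness. The esfenvalerate profile at 1 µg/L rests on 3 arrays.

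A score of the bifenthrin 1.6 µg/L signature, chosen after the data had been seen, was 2.38 higher in bifenthrin larvae of the 3 runs than in their controls (95% interval 2.06 to 2.70). All 32 arrays lay above the control median, and the permutation p of 1e-05, the smallest that 100000 permutations can give, was 0.00029 after adjustment. In the 2-dose experiment the difference was 0.51 for bifenthrin at 0.15 µg/L (95% interval -0.71 to 1.74). Esfenvalerate at 1 µg/L scored 2.01 above its own solvent controls on 3 of 3 arrays (exact p = 0.0045, adjusted p = 0.035), while its difference from all 34 controls did not pass the test (adjusted p = 0.27). Its own solvent controls had the lowest mean score of the 4 control sets, -1.04 ± 0.54 (SD, n = 9).

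**Figure D3:**
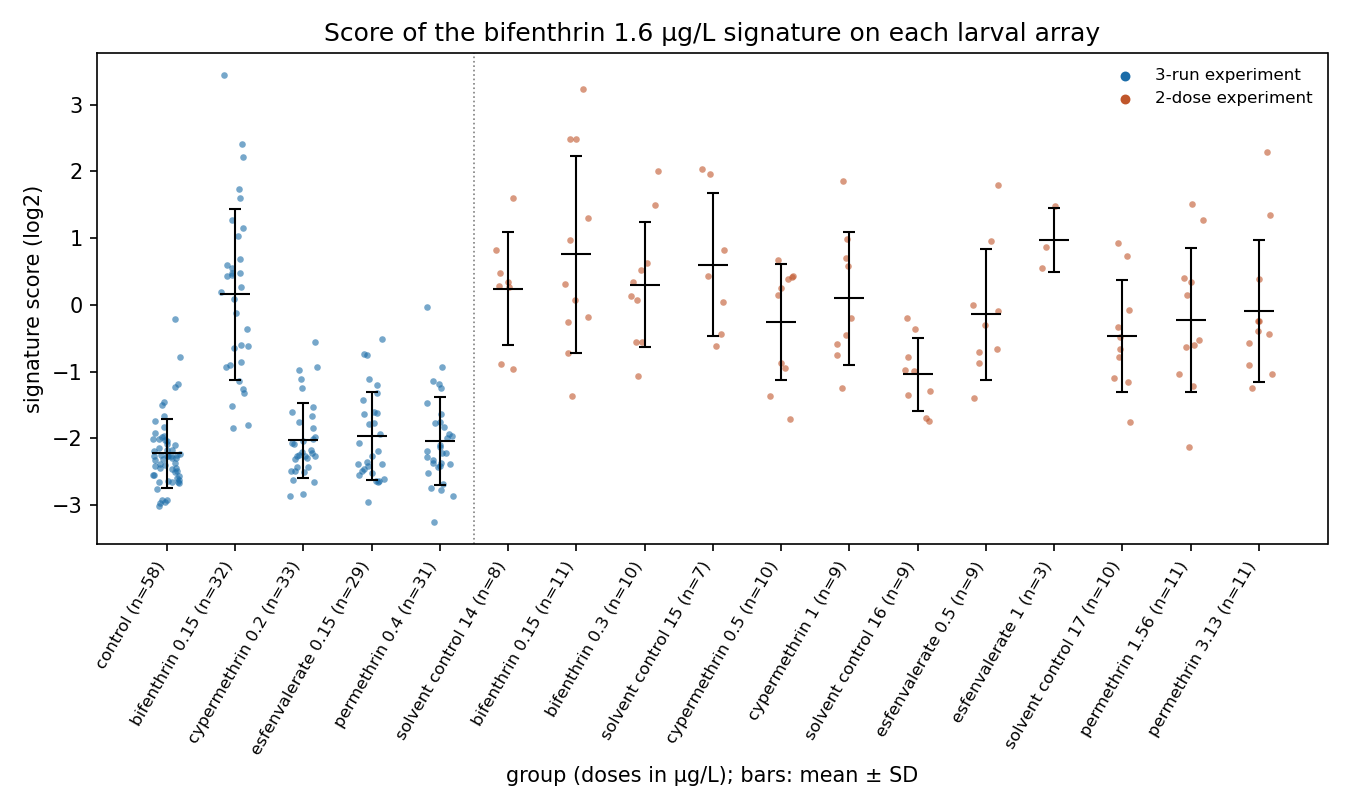
Score of the bifenthrin 1.6 µg/L signature (vertical axis, log2) on every array of the 3-run and 2-dose larval experiments, by group (horizontal axis, doses in µg/L); points are arrays, black lines means, bars SD. Bifenthrin larvae of the 3 runs average 0.16 against -2.23 in their controls, and the 34 solvent controls of the 2-dose experiment average -0.23.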

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

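The random regroupings of the 34 planned comparisons and the tests of fewer arrays and of the control level in the first pattern were set only after their results had been seen. The added comparisons (cypermethrin doses, solvent control sets, both bifenthrin experiments) were chosen after the planned counts had been seen but set, like the other tests, before their own values were.

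The effect of bifenthrin at 0.15 µg/L differed between the 2-dose and the 3-run larval experiment for 4557 probes in a joint fit with limma, and 100 regroupings gave no more than 541 otherwise (1 of 100, the real one). The separate fits had called 4 and 15036 probes, although all 34 solvent controls in place of the 8 of bifenthrin's own title number gave 6256 in the 2-dose experiment. Fewer arrays in the 2-dose experiment do not account for this, since runs thinned to its array numbers still gave at least 573 probes. A wider spread alone is argued against by the 4557 probes whose effects differ. All 34 solvent controls of the 2-dose experiment averaged 1.99 higher on the bifenthrin signature than those of the 3 runs, close to the 2.38 that bifenthrin added there. The 4 calls, however, used only the 8 controls of bifenthrin's own number. The signature probes were also picked separately from those kept in each experiment. Controls already near a bifenthrin-like level may account for part of the difference. A technical difference between the experiments could give the same offset, and no biological explanation was tested.

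Counts of the 2-dose experiment changed with the choice of solvent controls. The solvent controls of the 4 title numbers differed from each other for 26883 probes (limma F-test), and the 100 regroupings other than the real one (1 of 100) gave at most 0. With the slide as a block 20401 probes still differed, which argues against the slide as the whole cause. Without the block, the controls numbered 14, which are bifenthrin's own, stood furthest apart. They differed from numbers 15, 16 and 17 for 12454, 16865 and 22993 probes. Pairs among the other numbers differed for 4356, 3960 and 9217 probes. Treated arrays deviated together with the controls of their own number: the mean correlation was 0.58, against -0.18 for other pairings, and only 1 of the 24 pairings, the real one, was as high. This is consistent with a batch shared by all arrays of a title number, and comparisons across numbers then carry that batch, while a difference in the fish of each set stays open and untested.

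EE2 livers gave dimmer arrays than control livers. The slide is argued against, since the difference in the 75th percentile was -0.56 (95% interval -0.75 to -0.37) with the slide as a term. Background in dim probes does not account for the calls, as 44.5% of probes were called in the brightest of 3 equal groups and 18.8% in the dimmest. The 100 most raised probes took 3.4 percentage points more of the summed signal in EE2 livers, below the limit set for a few transcripts taking most of it. This share counts signal over probes and not amounts of RNA. It therefore cannot decide whether a few transcripts made up much of the labelled RNA. EE2 itself, as a biological cause, and the amount or quality of RNA per array were not tested apart and may both remain.

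Single arrays far from the rest of their group were found in 2 of 54 tests, where chance gives about 1 in 20. Each test took 1 group on 1 of 2 signature scores, of bifenthrin at 1.6 µg/L and of EE2 in liver. The smallest and the larger groups were not tested. On the score of the EE2 liver signature, replicate 6 of the larvae given bifenthrin at 0.148 µg/L stood at -0.57, with the nearest array at -0.30. Replicate 2 of the larvae given esfenvalerate at 0.5 µg/L stood at 0.04, with the nearest at -0.52. The effect of a chemical differed between runs for 74 probes.

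The regroupings of the planned comparisons were run before their reading was written down, so that the 5% limit was set after the results were seen. Random regroupings of the arrays, 100 per comparison with the real one included, tested whether chance could give as many calls. The smallest share they can give is 1 of 100. This share was not adjusted over the comparisons, and arrays were not kept within slides, so that chance is not excluded by it. Only 1 of 100 regroupings, the real one, was as high for EE2 in liver (9819 calls, highest other 6290), EE2 at 10 ng/L in brain (5, highest other 1), the EE2 dose trend (5, highest other 0), permethrin in brain (3, highest other 0) and the departure from additivity (8, highest other 1). The same held in larvae for bifenthrin at 0.3 µg/L (12250, highest other 346), cypermethrin at 0.5 µg/L (1257, highest other 379), permethrin at 3.13 µg/L (1866, highest other 119), bifenthrin in the 3 runs (15036, highest other 228), the interaction with the run (74, highest other 2) and bifenthrin at 1.6 µg/L (22193, highest other 3752). It held as well for bifenthrin against esfenvalerate (10535, highest other 740), cypermethrin against esfenvalerate at 0.5 µg/L (587, highest other 23) and cypermethrin at 0.5 against 1 µg/L (2434, highest other 6). For terbufos (45 calls) 2 of 100 regroupings were as high, the other giving 1936, and for EE2 at 1 ng/L (1 call) 3 of 100, reaching 2.

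Chance could not be excluded for bifenthrin at 0.15 µg/L in the 2-dose experiment (4 calls, 9 of 100 regroupings as high, highest other 565), cypermethrin at 1 µg/L (3 calls, 8 of 100, highest 521), esfenvalerate at 1 µg/L (8 calls, 45 of 100, highest 2343) and cypermethrin against esfenvalerate at 1 µg/L (8 calls, 14 of 100, highest 222). Where limma called 0 probes, all 100 regroupings were trivially as high. The highest other counts were 6768 for the mixture, 1176 for cypermethrin at 0.25 µg/L in brain, 438 for bifenthrin at 0.593 µg/L and 84 for cypermethrin at 1 µg/L in larvae of the smaller design, and 1445 for cypermethrin in the 3 runs. Regroupings that call many times the real count point to a structure among the arrays that the groups do not follow. Among the other comparisons with 0 calls the highest was 2 for EE2 at 0.1 ng/L, 0 and 1 for bifenthrin at 0.148 and 0.593 µg/L in brain and 2 for cypermethrin at 1 µg/L in brain. It was 1 each for bifenthrin at 0.148 and cypermethrin at 0.25 µg/L in larvae of the smaller design, 4 for esfenvalerate at 0.5 and 2 for permethrin at 1.56 µg/L in the 2-dose experiment, and 1 for esfenvalerate and 0 for permethrin in the 3 runs.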

How the results depend on the processing

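Outside the 1.6 µg/L experiment no pairing of single arrays could be fitted, since the labels give none. In that experiment the title number as replicate block gave 23095 calls, which lies within 1.5 times of the 22193 without it. The block still counts every array as a replicate. It therefore cannot show how many calls would remain if the title numbers, rather than the arrays, were the independent units. Of 262 alternative values of the comparisons, 182 kept within 1.5 times the reported count or on the same side of the threshold. The others follow, and the cause was not tested. Leaving out low-correlation arrays, leaving out bifenthrin, and the signature scores were chosen after seeing the data. The gene list alternatives were not run, for want of gene names, nor were the authors' deposited values for the dose trend, additivity, the interaction and the comparisons between chemicals, whose arrays lie in separately normalized tables. Signal over background limits the liver comparison most, where the median share of probes well above background was 54.9%.

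Without the filter on dim probes EE2 in liver gave 15788 calls, and bifenthrin at 0.15 µg/L in the 2-dose experiment gave 0. Slides 1 and 2 alone, with fewer arrays, gave 1090 and 3982 in liver. With the slide as a block the counts were 2 for EE2 at 0.1 ng/L, 0 at 1 ng/L, 1 for permethrin in brain, 0 for cypermethrin at 1 µg/L, 182 for permethrin at 3.13 µg/L, 128 for the interaction and 0 for cypermethrin against esfenvalerate at 1 µg/L.

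With normexp, EE2 at 1 ng/L gave 0, the dose trend 8, permethrin in brain 0, terbufos 68 and the departure from additivity 3. On larvae it gave 2 for cypermethrin at 1 µg/L on the smaller design and, in the 2-dose experiment, 0 for bifenthrin at 0.15 µg/L, 7259 at 0.3 µg/L, 1 for cypermethrin at 1 µg/L, 10 and 6312 for permethrin at 1.56 and 3.13 µg/L and 232 for cypermethrin against esfenvalerate at 0.5 µg/L. The interaction gave 44. Quantile normalization gave 5 for permethrin in brain, 1 for the mixture, 1 each for bifenthrin at 0.148 and cypermethrin at 1 µg/L in larvae of the smaller design, 24 for bifenthrin at 0.15 µg/L, 15 for esfenvalerate at 1 µg/L, 2923 for permethrin at 3.13 µg/L and 18 for cypermethrin against esfenvalerate at 1 µg/L.

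The authors' deposited values gave 8 for permethrin and 192 for terbufos in brain, 1 for the mixture, 0 for bifenthrin at 0.15 µg/L and for cypermethrin at 1 µg/L, 46 for esfenvalerate at 1 µg/L and 22 for permethrin at 3.13 µg/L. On the scan day with the most arrays alone, EE2 at 1 ng/L gave 0, terbufos 25, cypermethrin at 0.25 µg/L in brain 1, bifenthrin at 0.15 µg/L 24, cypermethrin at 0.5 and 1 µg/L 152 and 1, esfenvalerate at 0.5 µg/L 19, permethrin at 3.13 µg/L 0 and cypermethrin against esfenvalerate at 0.5 µg/L 242.

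With all 34 controls, bifenthrin gave 6256 at 0.15 and 2507 at 0.3 µg/L, cypermethrin 56 at 0.5 and 392 at 1 µg/L, and permethrin 4 at 1.56 and 0 at 3.13 µg/L. Cypermethrin against esfenvalerate, where pooled controls cancel out and treated arrays are compared directly, gave 0 at 0.5 and 845 at 1 µg/L. Without low-correlation arrays, terbufos gave 97, bifenthrin 0 at 0.15 and 7853 at 0.3 µg/L, cypermethrin 2047 at 0.5 and 7 at 1 µg/L, esfenvalerate 1 at 1 µg/L, permethrin 14 at 3.13 µg/L and the interaction 155. Leaving out single esfenvalerate arrays gave 0 to 17 for esfenvalerate at 1 µg/L and 0 to 27 for cypermethrin against it; replicate 2 left out gave the 0 in either case.

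Runs 1, 2 and 3 alone, with fewer arrays, gave 9286, 7392 and 4595 for bifenthrin and 4546, 5255 and 1794 for bifenthrin against esfenvalerate. Run 2 gave 1 for esfenvalerate, and runs 1 and 3 gave 9 and 1 for permethrin. The likeness between runs of 0.073 (p = 0.064) was 0.096 without low-correlation arrays (p = 0.014) and turned to -0.037 without bifenthrin (p = 0.94). With other measures, filters and runs left out it lay between 0.051 and 0.094, with p from 0.059 to 0.25. Of 39 alternative values of score differences that had passed the test, 29 passed again. With all 34 controls, 2 changed sign: the EE2 liver signature with bifenthrin at 0.3 µg/L (0.04 in place of -0.51) and the probes brighter in liver with permethrin at 3.13 µg/L (0.06 in place of -0.52).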

Other observations

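The sets and scores below were chosen after the data had been seen. The 100 probes with the largest excess of liver over brain signal, taken from unexposed fish of the EE2 experiments, were lower in bifenthrin larvae of 2 experiments, while in the 2-dose experiment the direction depended on the controls used. Their mean was 0.80 ± 0.57 (SD, n = 32) at 1.6 µg/L against 1.85 ± 0.45 (n = 33) in controls, a difference of -1.05 (95% interval -1.31 to -0.80, adjusted permutation p = 0.00029), and 0 of 32 arrays lay above the control median. In the 3 runs the difference was -0.22 (95% interval -0.31 to -0.13, adjusted permutation p = 0.00069), with 7 of 32 arrays above the control median. In the 2-dose experiment bifenthrin differed from its own solvent controls by 0.16 at 0.15 µg/L (adjusted p = 0.90) and by 1.11 at 0.3 µg/L (95% interval 0.31 to 1.92, adjusted p = 0.07), in the opposite direction, but from all 34 controls by -1.10 (adjusted permutation p = 0.055) and -0.14 (adjusted permutation p = 0.99). Permethrin at 3.13 µg/L gave -0.52 (95% interval -0.86 to -0.19, adjusted p = 0.035 from an exact test), with 0 of 11 arrays above the control median, yet 0.06 against all 34 controls. The 100 probes with the largest excess of brain over liver signal were higher by 0.14 with bifenthrin in the 3 runs (95% interval 0.09 to 0.19, adjusted permutation p = 0.00029, 29 of 32 arrays) and differed by -0.25 at 0.3 µg/L in the 2-dose experiment (95% interval -0.42 to -0.07, adjusted p = 0.025 from an exact test, 0 of 10 arrays above), where normexp (-0.23) and all 34 controls (-0.04) ended the latter call.

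Terbufos brains scored 0.53 higher than control brains on the larval bifenthrin signature (1.59 ± 0.32 against 1.06 ± 0.27, SD, n = 13 each, 95% interval 0.29 to 0.77, adjusted permutation p = 0.0038), with 12 of 13 arrays above the control median. UF_Ppr_AF_109937, a probe with a large rise in bifenthrin larvae, rose by 1.66 in terbufos brains (limma adjusted p = 0.047) and differed by 1.67 with the mixture (adjusted p = 0.40) and by -0.16 with permethrin (adjusted p = 0.82). EE2 brains scored higher on that signature by 0.29 at 0.1 ng/L and by 0.21 at 10 ng/L (adjusted permutation p = 0.025 and 0.032, 10 of 12 arrays each). At 1 ng/L the difference was 0.15 (95% interval -0.11 to 0.40, adjusted permutation p = 0.52, 6 of 12 arrays), so that the score did not rise with the dose, and the call at 10 ng/L was lost with normexp. Brains given cypermethrin at 1 µg/L differed by -0.27 (adjusted p = 0.044 from an exact test, 1 of 10 arrays above the control median), which normexp also ended.

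The EE2 liver signature was flat in EE2 brains, with a difference of 0.03 at 10 ng/L (95% interval -0.05 to 0.11, adjusted permutation p = 0.69, 6 of 12 arrays above the control median). In larvae of the 2-dose experiment it differed by -0.51 with bifenthrin at 0.3 µg/L (0 of 10 arrays above the control median) and by 0.28 with permethrin at 3.13 µg/L (10 of 11 arrays), each with an adjusted p of 0.0092 from exact tests. Both calls rest on the chemical's own solvent controls, since either difference was 0.04 against all 34 controls (adjusted permutation p = 0.99). Bifenthrin at 0.15 µg/L scored -0.12 relative to its own controls (adjusted p = 0.52, exact test) and 0.43 relative to all 34 (adjusted permutation p = 0.034). In the main setting 115 such differences were tested, and those against all 34 controls were adjusted as a separate set.

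The probe UF_Ppr_AF_109937 stood at 3.03 ± 2.01 (SD, n = 8), 4.19 ± 0.91 (n = 7), 2.23 ± 1.12 (n = 9) and 3.33 ± 1.43 (n = 10) in the solvent controls numbered 14 to 17 of the 2-dose experiment. It stood at 0.34 ± 1.79 (n = 58) in the controls of the 3 runs and at -0.37 ± 1.41 (n = 33) in those of the 1.6 µg/L experiment. Cypermethrin at 0.5 against 1 µg/L in the 2-dose experiment differed for 2434 probes, 1060 of them higher at the lower dose.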
